A study of Homo sapiens with 4 samples.

How the data were processed

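Drop-seq counts of 4 libraries were analysed, 1 per time point, from U937-derived macrophages before LPS and 2 h, 4 h and 6 h after it. Per the labels, cells received 50 ng/mL PMA for 48 h, rested for 24 h in medium with 10% serum, were given 100 ng/mL LPS, and were run on a custom Drop-seq device with Nextera XT libraries. The deposited values are raw UMI counts per gene symbol and cell barcode, 1 table per library, as tested on their values: whole numbers from 0, library sums that differ, and columns named by 12-base barcodes. The submitters' notes name the build hg19 and the tool Seurat without a version or a role. The aligner, the counting tool, the annotation and the rule that chose 500 or 1000 barcodes are not given in the sources used here. The tables hold 18632 gene symbols, 3500 barcodes and 5922945 UMIs, and 79.6% of the symbols matched a current or older gene name. No coordinates are given, since the symbols come from hg19 and the annotation at hand is of another build. Genes are named by the symbols of the tables, which list CXCL8 as IL8.

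Counts were summed over all barcodes of a library and divided by the library total (CPM). A gene was tallied as different when its CPM ratio was at least 2 in either direction, the exact conditional binomial (Clopper-Pearson) 95% interval of the ratio excluded 1, and the higher library had at least 30 UMIs and 50 CPM. A gene without a UMI in 1 library was set against a floor of 3 counts, and its ratio is given with the words at least. This bound ignores counting error in the other library, and the lower 95% limit of such a ratio is smaller. No p-value, standard error or test was possible with 1 library per time point. Each LPS library was compared with the basal library, and consecutive LPS libraries with each other. For genes tallied as higher in any LPS library, the LPS library with the highest CPM was recorded. The overlap of tallies was set against simulations in which no gene differed and only counting error was drawn.

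Named genes were chosen by rule: against basal the 12 largest and the 12 smallest ratios among tallied genes with at least 100 CPM in the higher library, for consecutive libraries the 6 largest and 6 smallest, then tallied members of the gene lists and the measured secreted effectors. Copies that share sequence took no place and are called uncertain. Some genes that the rule names are not reported here. There were 28 lists: secreted effectors, NF-kB targets and feedback, immediate early genes, interferon-stimulated genes, feedback and tolerance regulators, LPS receptor and TLR signalling, macrophage identity, promonocyte and granule genes, S phase, G2/M, antigen presentation, glycolysis, oxidative phosphorylation, cholesterol, lysosome, matrix and plasminogen, metallothioneins and oxidative stress, heat shock and unfolded protein, apoptosis, cytosolic ribosomal proteins, mitochondrially encoded genes, histones, and markers of T and NK cells, of B cells, of neutrophils, of dendritic cells, of erythroid cells and platelets, and of fibroblasts, epithelium and endothelium. A member was measured with at least 30 UMIs over both libraries. A list with at least 4 measured members was given a median log2 ratio and its percentile among 10000 random lists of the same size matched on expression in 20 bins. Some genes are in more than 1 list. These comparisons, lists, thresholds and most alternatives were chosen before the data were examined.

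For single barcodes, counts were thinned at random to 500 UMIs and shallower barcodes left out. From thinned counts came the share of barcodes with a UMI of an effector (Clopper-Pearson interval), the Fano factor with its percentile among the 100 genes of nearest mean, and Spearman's rho between effectors against 1000 shuffles of barcodes. Each library was clustered on its own with barcodes of at least 100 UMIs, normalised to 10000 UMIs, with 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 0.5. Clusters of the 4 libraries were matched as deep, MALAT1-rich and MT-RNR2-rich kinds after the clusters were seen, and the measurements within kinds were chosen then. The ratios that the mix alone would give came from the basal profile of each kind, weighted by the UMIs of the kinds in each library. No doublet caller was run, and an alternative without the 5% of barcodes with most UMIs stands in its place. Free RNA was not removed.

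The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, which was used for TMM factors alone. Alternatives were TMM and median-of-ratios scaling, a total without ribosomal protein and mitochondrial genes, the mean of per-cell CPM, stricter and looser minimums and fold thresholds, barcodes of at least 1000 or 2000 UMIs, no barcodes over 10% mitochondrial UMIs, libraries thinned to the smallest total, thinning to 1000 UMIs or none, other clustering settings, each kind of barcode alone, equal weights of the kinds, and each gene without the barcode holding most of its UMIs. On simulated data with known ratios, 42% to 62% of genes with a true 2-fold ratio were tallied, 94% to 100% of those with 3-fold, and at most 7 of 18432 unchanged genes. Those 18432 include genes too scarce to be tallied at all. The intervals held the true ratio for 95.4% to 95.8% of the 3019 to 3188 genes with enough expected counts. Of random unchanged lists, 3% to 8% fell outside the central 95% of random lists. The simulated counts hold counting error only, so this coverage follows from how they were drawn. They leave out UMIs clumped in single barcodes, so they do not measure false tallies from that source. The libraries held between 1025912 and 1759662 UMIs, and 3 counts correspond to between 1.70 and 2.92 CPM.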

Results

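RNA was measured in single human macrophages made from the U937 line, a leukocyte line of promonocytic cells that becomes adherent and macrophage-like with phorbol ester. The labels give 50 ng/mL PMA for 48 h and 24 h of rest, followed by 100 ng/mL LPS, a bacterial cell wall lipid sensed by TLR4. Drop-seq, which captures cells with barcoded beads in droplets and counts transcripts by unique molecular identifiers (UMIs), was run once at each of 4 time points. The basal library held 500 barcodes and 1025912 UMIs. The 2 h, 4 h and 6 h libraries each held 1000 barcodes, with 1419030, 1718341 and 1759662 UMIs. The median barcode had 1452 UMIs in the basal library, 861.5 at 2 h, 789.5 at 4 h and 1110.5 at 6 h. Genes detected numbered 14092, 14866, 14410 and 15532 in that order. With 1 library per time point there was no replicate check, and time cannot be told apart from differences between library preparations. Levels are UMI counts scaled to a library total of 1000000 (CPM), and every interval given is a 95% interval that covers counting error only. A count of 0 allowed up to 2.92 CPM in the basal library, 2.11 at 2 h, 1.75 at 4 h and 1.70 at 6 h.

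Clustering within each library gave 3 clusters in all 4 libraries at the setting fixed beforehand, and 3 kinds of barcode were matched across libraries by composition. No cluster was given a cell type name, and all are described by depth and composition. Of 7 interferon-responding markers, 3, 5, 4 and 6 were at least 2-fold higher in the deep cluster of the basal, 2 h, 4 h and 6 h libraries than in other barcodes, with at most 1 of them among its 10 leading genes. Deep barcodes had medians of 3349, 3692, 4256 and 2474 UMIs in the basal, 2 h, 4 h and 6 h libraries. MALAT1-rich barcodes had medians between 885 and 1336 UMIs, with 13.7% to 17.9% of their UMIs from the nuclear RNA MALAT1. MT-RNR2-rich barcodes had medians between 660 and 1177 UMIs, with 4.11% to 11.3% of UMIs from the mitochondrial ribosomal RNA MT-RNR2. This kind was not alike across libraries, with 6.99% MALAT1 and 4.11% MT-RNR2 in the basal library and 1.92% and 9.37% at 2 h, so its values against the basal library compare clusters of unlike composition. Deep barcodes supplied 40.1% of the UMIs of the basal library, 36.8% at 2 h, 56.8% at 4 h and 48.7% at 6 h. Ribosomal protein genes held 4.26% of the UMIs of deep barcodes in the basal library and 1.21% of those of MALAT1-rich barcodes. Summed levels mix these kinds, so tallies and gene groups were also measured within each kind.

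**Figure D1:**
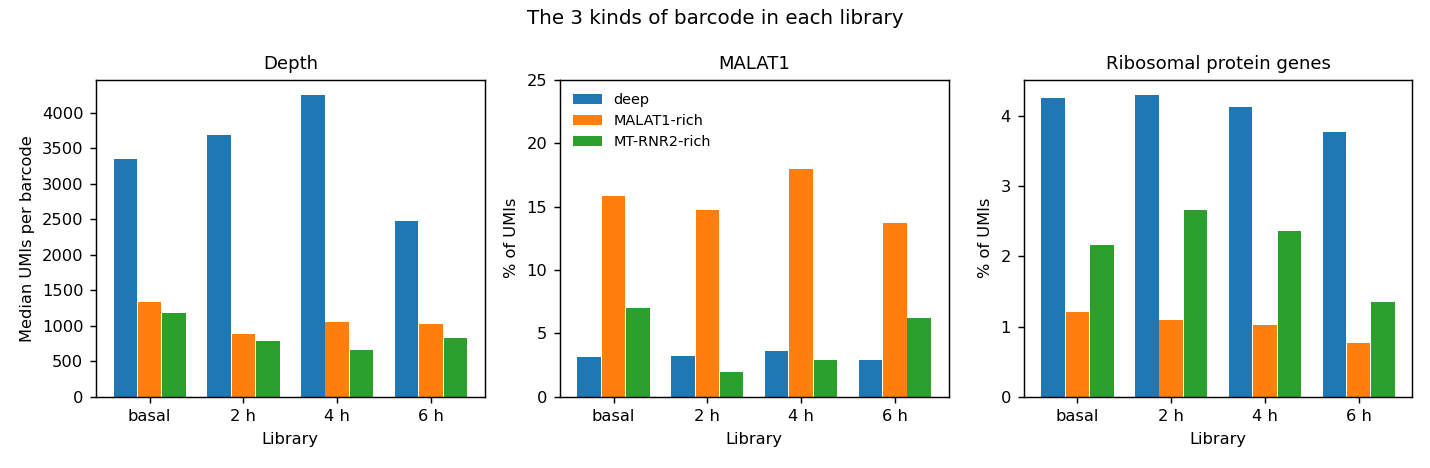
Median UMIs per barcode (left), percent of UMIs from MALAT1 (middle) and percent of UMIs from ribosomal protein genes (right) for the 3 kinds of barcode in each library. Bars are single values per library without error bars, and deep barcodes had at least 2474 UMIs at the median while the other kinds stayed at or below 1336.

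The 2 h library was compared with the basal library to find RNAs that differ early after LPS. Of 3588 genes with enough counts, 180 were at least 2-fold higher at 2 h and 78 at least 2-fold lower, and 2792 genes lay within 1.5-fold. CXCL3 had the largest ratio, with 752 CPM at 2 h against 10.7 CPM, a 70.1-fold difference (39.0 to 141). One barcode held 246 of its 1067 UMIs, and the ratio without it was 54.0. PTGS2 was 68.7-fold higher (23.3 to 335, from 3 basal UMIs), CCL4 59.1-fold, BIRC3 53.0-fold, IL1B 46.0-fold and TNF 45.6-fold (23.9 to 100). CSF2 had no UMI in the basal library and was at least 37.6-fold higher at 2 h. CCL20 (34.3-fold), TRAF1 (31.3-fold), TNFAIP6 (23.9-fold), TNFAIP3 (23.4-fold) and PDE4B (20.8-fold) completed the 12 largest ratios. CCL4L1, a copy close in sequence to CCL4, had a ratio of 31.5 and is uncertain for that reason. Among genes lower at 2 h, MMP3 had the smallest ratio, 0.121, but 138 of its 155 basal UMIs lay in 1 barcode, and without that barcode MMP3 was 1.11-fold higher at 2 h (0.578 to 2.17). The lncRNA AC079466.1 (0.359 of its basal level), NDUFA13 (0.385), LAGE3 (0.405), MRPL41 (0.424) and PFN1 (0.426) followed. SRSF7, COPE, CXorf21, MINOS1, ATP6V0D1 and RAB5C had ratios between 0.429 and 0.466. TMM scaling added 0.17 to each log2 ratio and gave 214 genes higher and 28 lower, and it took MINOS1, ATP6V0D1 and RAB5C out of the tally. Median-of-ratios scaling added 0.13 and gave 218 and 45. Without the 5% of barcodes with most UMIs, 202 genes were higher and 186 lower. Within deep barcodes 188 genes were higher and 64 lower, within MALAT1-rich barcodes 245 and 163, and within MT-RNR2-rich barcodes 98 and 94.

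At 4 h, the comparison with the basal library covered 3557 genes, of which 192 were higher and 367 lower. This balance depended on the scaling. TMM added 0.42 to each log2 ratio and turned it to 350 higher and 99 lower, and median-of-ratios scaling added 0.29 and gave 289 and 166. Deep barcodes alone gave 196 higher and 136 lower, MALAT1-rich barcodes 187 and 336, and MT-RNR2-rich barcodes 162 and 173. CCL4 reached 11205 CPM, 105-fold over its basal 107 CPM (86.7 to 127). BIRC3 was 101-fold higher (54.7 to 211), PTGS2 93.1-fold (31.7 to 453, from 3 basal UMIs) and CCL20 73.0-fold. TNIP3, without a UMI in the basal library, was at least 66.1-fold higher. CXCL3 (59.1-fold), TNFAIP6 (48.9-fold), IL1B (48.8-fold), PTX3 (44.8-fold, from 3 basal UMIs, 15.1 to 219), INHBA (32.9-fold), TRAF1 (31.5-fold) and CCL1 (21.3-fold) made up the other large ratios. The uncertain CCL4L1 had a ratio of 43.7. The smallest ratio was that of AC079466.1, 0.0943 of its basal level (0.0565 to 0.150). FAM101B (0.165), CYP4F3 (0.167) and PRAM1 (0.192) were also low, with TRERF1, SLA, NISCH, the phagocytic receptor gene MERTK, MTUS1 and the interferon-stimulated IFI44L between 0.206 and 0.236. MMP3 had a ratio of 0.212, and without the basal barcode that held 138 of 155 UMIs it was 1.93-fold higher at 4 h, with an interval above 1.

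At 6 h, 3642 genes were compared with the basal library, 253 of them higher and 221 lower. TMM, which added 0.19 to each log2 ratio, gave 318 and 113, and median-of-ratios scaling, which added 0.17, gave 331 and 142. The balance turned with the mean of per-cell CPM (263 and 320) and with equal weights of the kinds (247 and 329). It also turned without the 5% of barcodes with most UMIs (255 and 304). With barcodes of at least 1000 UMIs it kept its side (241 and 225). Deep barcodes gave 292 and 198, MALAT1-rich barcodes 277 and 258, and MT-RNR2-rich barcodes 107 and 254. PTGS2 was 103-fold higher (35.1 to 502), TNIP3 at least 85.5-fold, IL1B 70.0-fold (52.2 to 96.1) and IL18R1 67.9-fold, the last from 2 basal UMIs (18.6 to 564). PTX3 (59.7-fold, 20.2 to 291), CCL4 (57.3-fold), INHBA (54.9-fold), BIRC3 (53.5-fold), CXCL3 (40.1-fold), CCL20 (39.5-fold), CCL1 (34.7-fold) and TNFAIP6 (31.6-fold) came next. FAM101B had the smallest ratio, 0.0762 (0.0431 to 0.127), followed by AC079466.1 (0.105), the lipid droplet gene PLIN2 (0.185), APBB1IP (0.185), MTUS1 (0.191) and DHRS3 (0.215). SLA, the interferon-inducible MNDA, CYP4F3, GCHFR, ITGA4 and PCM1 lay between 0.240 and 0.282. MNDA was abundant, at 1683 CPM in the basal library and 409 CPM at 6 h.

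Consecutive libraries were compared to separate early from later differences. From 2 h to 4 h, 83 of 3320 genes were higher at 4 h and 165 lower. TMM, with a shift of 0.25, gave 178 and 84, and median-of-ratios scaling, with 0.16, gave 133 and 114. Deep barcodes gave 76 and 218, MALAT1-rich barcodes 40 and 174, and MT-RNR2-rich barcodes 95 and 82. CCL1 was 9.22-fold higher at 4 h than at 2 h, TNIP3 7.22-fold, TM4SF1 4.95-fold, RGS16 4.82-fold, HLX 3.46-fold and MAP3K5 3.27-fold. TNF was among the genes lower at 4 h, at 0.222 of its 2 h level (0.185 to 0.266), with KB-1507C5.4 (0.158), FAM101B (0.159), MTUS1 (0.204), FFAR2 (0.242) and SH3PXD2A (0.266). Between 4 h and 6 h, 178 of 3310 genes were higher at 6 h and 47 lower. TMM, with a shift of -0.23 here, turned this to 75 and 151, and median-of-ratios scaling, with -0.12, gave 139 and 94. Deep barcodes gave 98 and 28 and MALAT1-rich barcodes 182 and 51, but MT-RNR2-rich barcodes turned the balance to 61 and 188. MMP3 was 4.92-fold higher at 6 h than at 4 h and MMP10 3.29-fold. Single barcodes held 80 of 277 MMP3 UMIs and 62 of 202 MMP10 UMIs at 6 h, and without them the ratios were 3.50 and 2.28. ZFP36L2 (3.43-fold), KIAA1551 (3.42-fold), RFX8 (3.36-fold) and C5AR2 (3.10-fold) were also higher. IL10 stood at 0.181 of its 4 h level at 6 h (0.151 to 0.215), NFKBIA at 0.281, GADD45B at 0.319 and TRAF1 at 0.376. NUPR1 (0.238) and PLIN2 (0.318) rested on single barcodes of the 4 h library, which held 165 of 230 NUPR1 UMIs and 222 of 442 PLIN2 UMIs. Without them the ratio of NUPR1 was 0.841 (0.578 to 1.22) and that of PLIN2 0.639 (0.514 to 0.792).

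Among the 347 genes at least 2-fold higher than basal in any LPS library, 101 had their highest level at 2 h, 81 at 4 h and 165 at 6 h. The interval against the next highest LPS library excluded equality for 73, 48 and 116 of them. TMM scaling gave 232 genes with the highest level at 4 h and median-of-ratios scaling 162, because both raise the 4 h library. Of these 347 genes, 101 were at least 2-fold higher in all 3 LPS libraries. The 2 h and 4 h libraries shared 117 higher genes, where independent lists would share 6.99, and the 4 h and 6 h libraries shared 151 against 10.6. All 3 LPS libraries shared 24 lower genes out of 497, among them LMO2, KCTD12 and SASH3, which are examples picked after their values were seen. The comparisons share the basal library, and in 100 simulations of unchanged genes with that sharing at most 1 gene overlapped. These simulations hold counting error only. They leave out UMIs clumped in single barcodes, the mix of kinds and library preparation, so they cannot tell how many shared genes those would give.

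**Figure D2:**
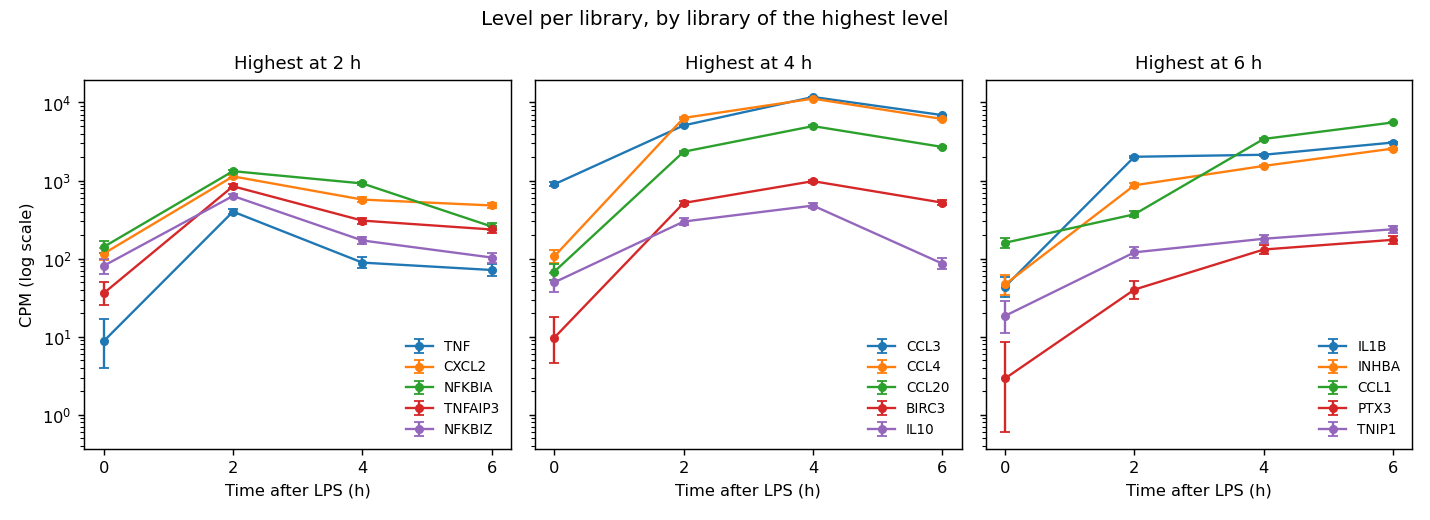
Level in CPM on a log scale against hours after LPS for 15 genes, grouped by the LPS library with the highest level. Points are single libraries, error bars are 95% counting intervals, and TNF stood at 400 CPM at 2 h, CCL3 at 11761 CPM at 4 h and IL1B at 3070 CPM at 6 h.

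Secreted effectors, the class that the series title concerns, were measured here as RNA. Of the list's 54 genes, 29 had enough counts at 2 h, and 16 were at least 2-fold higher than basal and 0 lower. At 4 h 14 of 29 were higher and 0 lower, and at 6 h 14 of 31 were higher and 2 lower. The median log2 ratio of the list was 2.40 at 2 h, 2.30 at 4 h and 2.05 at 6 h, above each of 10000 random lists matched on expression. The size of these medians depended on the members without a basal UMI, and over the 27, 26 and 28 members with one they were 1.64, 1.08 and 1.51. The list also lay above all random lists within each kind of barcode, with medians between 1.24 and 2.31. Of the 17 effectors higher than basal in any library, 7 were highest at 2 h, 7 at 4 h and 3 at 6 h. TNF had 8.77 CPM in the basal library, 400 at 2 h, 89.0 at 4 h and 71.6 at 6 h. CXCL2 was also highest at 2 h (1131 CPM), as were IL18 (231 CPM), OSM (137 CPM) and CSF2 (110 CPM). IFNB1 was also highest at 2 h, with 53 of its 76 UMIs in 1 barcode. CXCL3 at 2 h led its 4 h level by 1.19-fold, and this order is uncertain. Without the barcode with most of its UMIs in each library, the ratio to basal was 54.0 at 2 h and 55.7 at 4 h. The TMM shift of 0.25 for 4 h against 2 h also offsets the lead. CCL3 had 897 CPM in the basal library, 5084 at 2 h, 11761 at 4 h and 6890 at 6 h, and CCL20 followed the same order, with 4982 CPM at 4 h. CXCL8, listed under its older symbol IL8, had 449 CPM in the basal library and 6029, 6799 and 6576 CPM after LPS. IL10 and IL1RN were both highest at 4 h, at 478 and 2461 CPM. IL10 was 86.4 CPM at 6 h whereas IL1RN was 2336 CPM. CCL5 had 511 CPM in the basal library, 2713 at 4 h and 2693 at 6 h. IL1B and VEGFA were highest at 6 h, VEGFA at 529 CPM against 161 CPM in the basal library. IL6 was scarce but higher after LPS, with 1.95 CPM in the basal library and 47.7 CPM at 6 h, under the 50 CPM that the tally requires. Without thinning it was found in 1 of 500 basal barcodes and 28 of 1000 at 6 h. IL23A, with no basal UMI, was at least 33.8-fold higher at 6 h, where 1 barcode held 109 of its 174 UMIs, and without that barcode at least 12.6-fold. At 4 h, without its top barcode there, IL23A was at least 25.3-fold higher. Its place among the 3 effectors highest at 6 h therefore rests on 1 barcode. CXCL10 and CXCL11 were lower at 6 h, at 0.450 and 0.487 of their basal levels. Neither remained in the tally after TMM or median-of-ratios scaling, and without 1 barcode the CXCL10 ratio was 0.524. CCL2 (3818 CPM basal, 5164 CPM at 6 h) and SPP1 (31714 CPM basal, 41707 CPM at 6 h) were abundant in every library and differed by less than 2-fold.

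Targets and feedback genes of NF-kB also lay above all random lists at the 3 times. At 2 h 22 of 35 were at least 2-fold higher, at 4 h 23 and at 6 h 20, and 0 were lower at any time. Their median log2 ratio was 2.12, 2.15 and 1.65. Members differed in timing. NFKBIA had 141 CPM in the basal library, 1320 at 2 h, 919 at 4 h and 258 at 6 h, and TNFAIP3 had 36.1, 846, 307 and 236 CPM. NFKBIZ was 7.85-fold higher at 2 h and 2.11-fold at 4 h. SOD2 was 9.28-fold higher at 2 h, 16.4-fold at 4 h and 15.4-fold at 6 h, and TNIP1 6.51-fold, 9.71-fold and 12.9-fold. MARCKS had 1 basal UMI and 86.1 CPM at 4 h. Immediate early genes had a median log2 ratio of 0.44 at 2 h, with 11 of 30 higher and 2 lower, and 0.13 at 4 h and 0.18 at 6 h. NR4A3 was 7.06-fold higher and ZFP36 3.54-fold at 2 h, IER3 5.96-fold, and FOS and TRIB1 were lower, at 0.439 and 0.391. BTG2 was highest at 6 h, 15.2-fold over basal. Feedback and tolerance regulators, likewise above all random lists at the 3 times, had median log2 ratios of 1.15 at 2 h and 1.59 at 4 h and a median ratio of 2.15 at 6 h, with 8 of 17 members higher at 2 h, 9 of 19 at 4 h and 6 of 20 at 6 h. Over members with a basal UMI the log2 medians at 4 h and 6 h were 1.26 and 0.96. SOCS3 (5.12-fold) and CD274 (16.6-fold) were higher at 4 h, DUSP1 2.85-fold at 2 h and ZC3H12A between 5.34-fold and 7.57-fold over the 3 times. The LPS receptor and TLR signalling list had medians of -0.01, -0.61 and 0.03, with MYD88 at 0.378 of basal at 4 h and TLR2 2.30-fold higher at 6 h.

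Interferon-stimulated genes were lower at 4 h and 6 h, with a median log2 ratio of -0.65 and -0.56 over 44 genes, and had a median of -0.25 at 2 h. At 4 h and 6 h this was below each of the random lists, and at 2 h it was at percentile 1.01. Members at least 2-fold lower numbered 0 at 2 h, 7 at 4 h and 11 at 6 h, and the higher ones were IRF1 (2.93-fold) and GBP2 (2.21-fold) at 2 h and IFIT2 (2.03-fold) at 4 h. TMM scaling gave 6 lower members at 6 h and median-of-ratios scaling 7. RSAD2 stood at 0.332 of basal at 4 h and 0.422 at 6 h, TRIM22 at 0.299 and 0.366, CMPK2 at 0.344 and 0.365, and IFI44L at 0.236 and 0.376. ISG15 had 5316 CPM in the basal library and 3600 CPM at 6 h. Within MT-RNR2-rich barcodes 20 members were lower at 4 h and 22 at 6 h, with medians of -1.08 and -1.19. Deep barcodes gave medians of -0.54 and -0.52 and MALAT1-rich barcodes -0.41 and -0.50. At 2 h the list lay close to random lists within deep (-0.07, percentile 35.6) and MALAT1-rich barcodes (-0.10, percentile 31.4), and the median was -0.55 in MT-RNR2-rich barcodes. IFNB1, an inducer of these genes, had 1 UMI in the basal library, 76 at 2 h and 0 at 4 h and 6 h. Its UMIs at 2 h lay in 8 barcodes.

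Nuclear genes of oxidative phosphorylation had a median log2 ratio of -0.42 at 2 h and -0.57 at 6 h, each below all random lists, and 0.01 at 4 h (percentile 61.5). TMM leaves the medians at 2 h and 6 h negative and raises that at 4 h by its shift of 0.42. Among 47 genes, 6 had a ratio above 1 at 2 h and 2 at 6 h, and 3 were at least 2-fold lower at each of these times, NDUFA13 at both. The level at 4 h depended on the mix of kinds, which alone would give the list 0.26. Within kinds, the 4 h median was -0.28 in deep, -0.34 in MALAT1-rich and -0.25 in MT-RNR2-rich barcodes. Mitochondrially encoded genes had medians of -0.03 at 2 h, -0.88 at 4 h and -0.18 at 6 h, and 6 of 15 were at least 2-fold lower at 4 h, MT-ATP8 the lowest at 0.322. This count depended on the mix of kinds, since 0 members were lower at 4 h in deep (median -0.32), 1 in MALAT1-rich (-0.39) and 10 in MT-RNR2-rich barcodes (-1.22), and 2 with equal weights of the kinds. Cytosolic ribosomal protein genes had medians of -0.13, 0.19 and -0.25, with 0 members past 2-fold, and the sign at 2 h turned under TMM. Their value at 4 h also depended on the mix of kinds, which alone would give 0.26, and equal weights of the kinds gave -0.06. Glycolysis genes had medians of -0.38 at 2 h (percentile 0.660), -0.05 at 4 h and -0.25 at 6 h. PFKFB3 was higher at 4 h and 6 h, 2.78-fold at the latter, SLC2A3 2.38-fold at 6 h and ADM 5.20-fold at 2 h.

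Matrix and plasminogen genes had medians of 0.30 at 2 h, 0.54 at 4 h and 0.93 at 6 h, at or above percentile 99.9. PLAU was 3.35-fold, 3.31-fold and 9.12-fold higher, and MMP7, at 952 CPM in the basal library, 2.25-fold, 2.13-fold and 2.55-fold. MMP10 was 7.36-fold higher at 6 h and SERPINB2 between 2.06-fold and 2.71-fold over the 3 times. Metallothionein and oxidative stress genes had medians of 0.03, 0.63 and 0.46, with SLC7A11 4.61-fold, GCLM 3.35-fold and TXNRD1 2.53-fold higher at 6 h. The mix of kinds alone would give this list 0.20 at 4 h and leave 0.28. Cholesterol genes had medians of 0.08, 0.20 and 0.05, and INSIG1 was 2.71-fold, 6.45-fold and 3.39-fold higher. With the ratio from the mix of kinds taken off each gene, the cholesterol median at 4 h was -0.03. Apoptosis regulators had medians of -0.05, 0.08 and 0.06, while PMAIP1 was 4.94-fold, 13.9-fold and 16.8-fold higher and BCL2L11 3.43-fold, 3.92-fold and 3.14-fold. Macrophage identity genes had medians of -0.02, 0.19 and -0.06. The mix of kinds alone would give the macrophage identity list 0.14 at 4 h and leave 0.04. FABP5 was lower at 4 h (0.431) and 6 h (0.270), FABP4 at 6 h (0.406), and FCGR2A was 3.80-fold and CEBPB 2.22-fold higher at 6 h. Heat shock and unfolded protein genes had medians of -0.11, -0.18 and -0.13, with XBP1 3.20-fold higher at 2 h. Lysosome genes had medians of 0.06, -0.18 and -0.09 and antigen presentation genes of -0.13, -0.12 and -0.19, with PSMB8 at 0.428 and PSMB9 at 0.426 of basal at 6 h.

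**Figure D3:**
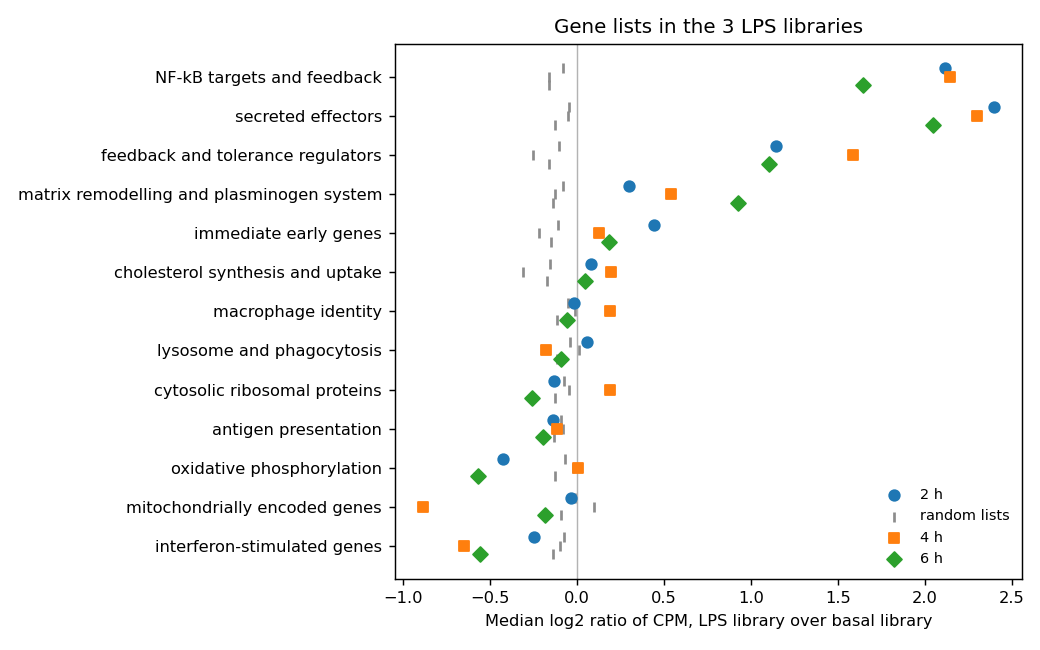
Median log2 ratio of CPM to the basal library for 13 gene lists (horizontal axis, lists on the vertical axis) in the 3 LPS libraries. Coloured points are list medians, grey ticks are medians of 10000 random lists matched on expression, no error bars are drawn, and NF-kB targets lay at 2.12, 2.15 and 1.65 while interferon-stimulated genes lay at -0.25, -0.65 and -0.56.

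S phase genes had medians of 0.29, -0.65 and -0.27 and G2/M genes of -0.30, -0.52 and -0.33, with 0 members past 2-fold and random lists of like expression at -0.43 and -0.38 at 4 h. Histone genes had medians of -0.51, -0.32 and -0.31, and promonocyte and granule genes -0.34, 0.43 and -0.03, with CEBPE at 0.335 of basal at 6 h. The mix of kinds alone would give the promonocyte and granule list 0.13 at 4 h and leave 0.26. The marker lists of other cell types had fewer than 4 measured members each. T and NK cell markers had 3, of which IL7R was 2.68-fold higher at 6 h, neutrophil markers 2, dendritic cell markers 1 at 2 h and 4 h and 2 at 6 h, and erythroid and platelet markers 1, the chemokine gene PPBP, at 49.7 CPM in the basal library and 178 CPM at 4 h. B cell markers and the fibroblast, epithelial and endothelial markers had 0.

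To compare how many cells held an effector's RNA at equal depth, each barcode was thinned to 500 UMIs, which left out 1, 63, 58 and 16 barcodes. CCL4 was found in 4.41% of basal barcodes (2.78 to 6.60), 89.5% at 2 h, 93.8% at 4 h and 75.2% at 6 h. Without thinning these shares were 11.8%, 96.3%, 98.5% and 91.0%. CCL3 was found in 25.3%, 84.4%, 95.5% and 82.7%, and CXCL8 (IL8) in 18.8%, 87.2%, 90.1% and 82.1%. IL1B was found in 3.21% of basal barcodes and 48.7%, 53.9% and 55.4% after LPS, against 7.80%, 66.8%, 70.5% and 75.8% without thinning. CCL20 was in 3.01%, 56.5%, 79.4% and 52.6%. TNF was found in 0.802% of barcodes in the basal library, 17.2% at 2 h (14.8 to 19.8), 5.52% at 4 h and 3.86% at 6 h, or 1.80%, 30.8%, 10.4% and 8.70% without thinning. IL10 was in 2.40%, 12.2%, 21.4% and 4.47%. CSF2 was in 0 of 499 basal barcodes, which by 3 counts allows a share of up to 0.601% with a UMI at this depth, and in 5.87%, 3.82% and 2.64% after LPS. CXCL10 was in 11.6%, 14.4%, 7.43% and 4.27%. SPP1 was in at least 99.6% of barcodes in every library. Droplets also carry free RNA, and no cell type that should lack these genes is present, so shares of abundant RNAs such as CCL4 after LPS include an unknown part from other cells.

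Spread between barcodes was described by the Fano factor, which is 1 for Poisson sampling of thinned counts. CXCL10 had 2.51 in the basal library, 2.21 at 2 h, 3.11 at 4 h and 3.50 at 6 h, above all 100 genes of nearest mean in each library. SPP1 had 11.9, 6.95, 8.09 and 12.5. CCL4 had 1.04, 2.25, 3.15 and 3.70, and CXCL8 (IL8) 1.37, 2.31, 2.37 and 3.84. The Fano factor rises with the mean at equal relative spread, and the mean thinned count of CCL4 was 0.0461, 3.27, 5.31 and 2.51. No change of relative spread is read from such series. IL10 and IL18 at 2 h (1.45 and 1.48) lay above all genes of like mean, and TNF at 2 h had 1.19. In the basal library CCL7 (3.14) and CCL8 (3.35) lay at or above percentile 98. Within kinds, CXCL10 was unevenly placed, at 759 CPM in deep, 177 in MALAT1-rich and 957 in MT-RNR2-rich basal barcodes.

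Co-detection of effectors within barcodes was measured by Spearman's rho on thinned counts. Each pair was set against the central 95% of its 1000 shuffles of barcodes, outside which some pairs fall by chance alone. The 78 pairs of 13 effectors in the basal library had a median rho of 0.02, and 17 lay above and 1 below this range. At 2 h 190 pairs had a median of 0.05, with 80 above and 14 below, at 4 h 153 pairs 0.08, with 84 and 5, and at 6 h 120 pairs 0.08, with 66 and 7. Thinned to 1000 UMIs, with more effectors, the medians were 0.0418 in the basal library and 0.0547, 0.0385 and 0.0716 at 2 h, 4 h and 6 h, so no order of the libraries is read from them. CCL3 and CCL4 formed the pair with the highest rho in each LPS library, 0.35, 0.51 and 0.42, and CCL2 and CCL7 did in the basal library, at 0.25. CCL2 and IL18 had the lowest rho at 2 h, -0.16, and CCL3 and VEGFA at 4 h, -0.12. The pairs were not measured within the 3 kinds of barcode.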

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

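The tests chosen only after the data were seen are those within each kind of barcode, with equal weights of the kinds, with barcodes of at least 2000 UMIs, without the barcode holding most of a gene's UMIs, and with another clustering seed. No paired analysis was possible because each time point had 1 library. Values for tallies are given as higher and lower genes, and the cause was not tested unless stated.

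Of 180 values of the gene tallies under alternatives, 106 stayed within 1.5 times the count reported and 74 moved. Thresholds moved every tally by construction. With 10 UMIs and no CPM minimum the tallies were 395 and 445 at 2 h, 356 and 1376 at 4 h, 564 and 696 at 6 h, 195 and 776 for 4 h against 2 h, and 957 and 145 for 6 h against 4 h. With 100 UMIs and 200 CPM they were 72 and 5, 75 and 49, 91 and 51, 32 and 37, and 34 and 15 in that order. A 1.5-fold threshold gave 324 and 471, 329 and 918, 458 and 764, 301 and 609, and 627 and 323. A 3-fold threshold gave 95 and 6, 104 and 75, 112 and 40, 18 and 34, and 13 and 6.

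Scaling by TMM moves every gene alike, which by construction gave 28 lower at 2 h, 350 and 99 at 4 h, 113 lower at 6 h, 178 and 84 for 4 h against 2 h, and 75 and 151 for 6 h against 4 h. Median-of-ratios scaling gave 45 lower at 2 h, 289 and 166 at 4 h, 142 lower at 6 h, 133 higher for 4 h against 2 h, and 94 lower for 6 h against 4 h. The mean of per-cell CPM gave 177 lower at 2 h, and 342 and 102 for 6 h against 4 h. Without the 5% of barcodes with most UMIs, 186 were lower at 2 h and 71 at 6 h against 4 h. Barcodes of at least 2000 UMIs gave 281 lower for 4 h against 2 h. A total without ribosomal protein and mitochondrial genes, barcodes of at least 1000 UMIs, no barcodes over 10% mitochondrial UMIs and thinned libraries kept all 10 tallies within 1.5 times.

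Deep barcodes alone gave 136 lower at 4 h, and 98 and 28 for 6 h against 4 h. MALAT1-rich barcodes gave 163 lower at 2 h and 40 higher for 4 h against 2 h. MT-RNR2-rich barcodes gave 98 higher at 2 h, 173 lower at 4 h, 107 higher at 6 h, 82 lower for 4 h against 2 h, and 61 and 188 for 6 h against 4 h. Equal weights of the kinds gave 101 lower for 4 h against 2 h and 74 higher for 6 h against 4 h. Leaving out the barcode with most of a gene's UMIs gave 28 lower for 6 h against 4 h. Each kind holds fewer UMIs than its library, which alone lowers the number of genes past the minimums.

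The numbers of genes with the highest level at each time moved in 5 of 39 values. TMM gave 232 at 4 h and median-of-ratios scaling 162. MALAT1-rich barcodes gave 154 at 2 h, and MT-RNR2-rich barcodes 51 at 2 h and 91 at 6 h.

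For list members, 117 of 126 values stayed within 1.5 times. In MT-RNR2-rich barcodes 11 NF-kB members were higher at 2 h and 12 at 6 h, and 4, 20 and 22 interferon-stimulated members were lower at 2 h, 4 h and 6 h. At 2 h 1 interferon-stimulated member was lower in deep barcodes and 1 in barcodes of at least 2000 UMIs. At 6 h TMM gave 6 lower members and median-of-ratios scaling 7. Of 432 values of list medians, 387 kept their side of the random lists and stayed outside the central 95% of them, and 45 did not. The effectors, NF-kB and interferon-stimulated medians at the 3 times, and those of oxidative phosphorylation at 2 h and 6 h, kept their side of the random lists under every alternative run. Keeping a side does not mean staying outside the central 95%. At 2 h the interferon-stimulated list lay only -0.03 and -0.04 from random lists in deep and MALAT1-rich barcodes. The 2 h gap of oxidative phosphorylation in MT-RNR2-rich barcodes was -0.08 (-0.30 to 0.04 over list members). The oxidative phosphorylation median at 4 h lay 0.03 above random lists over all barcodes and -0.14, -0.13 and -0.13 from them in deep, MALAT1-rich and MT-RNR2-rich barcodes. Among the 31 list medians tested, those that changed side at 4 h were apoptosis regulators, 0.30 above random lists as reported and -0.02 with the mean of per-cell CPM, and ribosomal protein genes, 0.24 and -0.05 in MALAT1-rich barcodes. Outside these 31, the TLR signalling median at 4 h was -0.61 against -0.31 for random lists and 0.04 against -0.33 in MT-RNR2-rich barcodes. Glycolysis at 4 h was -0.05 against -0.18, and -0.62 against -0.18 in MALAT1-rich barcodes.

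The 98 named ratios gave 1372 values, of which 1163 stayed inside the counting interval of the ratio reported, 201 left it and 8 reversed. MMP3 at 2 h had log2 ratios of 1.65 in deep barcodes, 0.71 in MT-RNR2-rich barcodes and 0.14 without its top barcode, and at 4 h 2.07, 1.73 and 0.95, since 1 basal barcode held most of its UMIs. NUPR1 for 6 h against 4 h had 0.52 in MALAT1-rich and 0.82 in MT-RNR2-rich barcodes, where the deep barcode with most of its UMIs is absent by construction.

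Clusters numbered 6, 5, 6 and 7 at resolution 1.0 in the basal, 2 h, 4 h and 6 h libraries. At resolution 0.3 the basal library had 2. Without barcodes over 10% mitochondrial UMIs the 2 h library had 4 and the 6 h library 2. The number stayed at 3 in the other libraries under these settings, and in all libraries with 1000 variable genes and with another seed. Shares of cells left the binomial interval of the share reported in 200 of 240 values. More UMIs per barcode find a gene more often, but thinning to 1000 UMIs also left out more barcodes. Some shares fell there, such as that of CCL20 at 4 h, from 79.4% to 78.5%. Of 192 Fano factors 57 moved by over 1.5 times, and 56 of these were among the 96 thinned to 1000 UMIs. Median co-detection rho, thinned to 1000 UMIs, went from 0.0206 to 0.0418 in the basal library and from 0.0789 to 0.0385 at 4 h, so the order of the libraries was not kept. Depth limits ratios of scarce genes, as 3 counts in the basal library are 2.92 CPM. True 2-fold differences were tallied in 42% to 62% of simulated genes, but this share does not measure depth. The tally asks for an observed ratio of at least 2, and the changed genes were drawn from those with at least 30 expected UMIs and 50 CPM.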

Other observations

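The tests of scaling and of barcode mix were chosen only after the results were seen. Those of transcript length, free RNA and loss of cytoplasm were set before their results. Where these concern the kinds of barcode, the clusters had already been seen. IFNB1 was found in 8 barcodes at 2 h, and 1 of them held 53 of 76 UMIs. CSF2 at 6 h was in 44 barcodes (33 of 131 UMIs in 1) and IL23A in 47 (109 of 174). Both were spread more widely before, CSF2 over 99 barcodes at 2 h (at most 7 of 156 UMIs in 1) and 64 at 4 h (8 of 99), IL23A over 72 at 2 h (5 of 93) and 92 at 4 h (17 of 144). Without its top barcode CSF2 remained at least 19.0-fold higher at 6 h than in the basal library. TNF at 2 h had 356 CPM in deep, 481 in MALAT1-rich and 311 in MT-RNR2-rich barcodes, whereas CCL4 had 7359, 4618 and 8110 CPM.

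Some genes, picked after their values were seen, had a late order. PLAU, SLC7A11, PMAIP1 and IL7R each had higher levels at 6 h than at 2 h, SLC7A11 with 211 and 733 CPM and PMAIP1 with 226 and 768 CPM. Of 8 matrix genes higher than basal in any library, 6 were highest at 6 h and 2 at 4 h, while of 12 immediate early genes 8 were highest at 2 h.

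Interferon-stimulated genes were lower at 4 h and 6 h. Scaling alone would have moved random lists of like expression as far, but the list lay at least 0.42 below them on the log2 scale (-0.42 at 6 h, -0.55 at 4 h). Another mix of barcode kinds would have left the list level with random lists within kinds. The smallest gap within a kind was -0.27 (-0.56 to -0.03 over list members), in MALAT1-rich barcodes at 4 h. A shift of composition inside a kind is not covered by this comparison. At 2 h the mix alone would give the list -0.00462 and leave -0.24 (-0.33 to -0.03 over list members), but scaling cannot be told apart there, as the gap to random lists was -0.17 (-0.27 to 0.04), and within kinds it was -0.54 only in MT-RNR2-rich barcodes, a cluster unlike its basal match, against -0.0317 in deep and -0.0373 in MALAT1-rich barcodes. Library preparation cannot be told apart from time with 1 library each, and time after LPS, the biological difference of the design, stays open and untested apart from it.

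Oxidative phosphorylation genes were lower at 2 h and 6 h than at 4 h, where they lay level with random lists over all barcodes. That level is consistent with the mix of kinds, which alone would give the list 0.26 at 4 h and without which it lay at -0.11 (-0.20 to -0.06) from random lists, with gaps of -0.14 in deep, -0.13 in MALAT1-rich and -0.13 in MT-RNR2-rich barcodes. The mix does not account for the whole difference from the other times, since within kinds the 4 h library lay above the mean of 2 h and 6 h by 0.25, 0.42 and 0.21 in that order, although in the last kind the 2 h gap of -0.08 was no lower than that at 4 h. Transcript length does not account for the low values, as the list stayed at least 0.33 below random lists matched on length (-0.33 at 2 h, -0.43 at 6 h). Library preparation remains open, and a biological change with time was not tested apart from it.

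At the setting fixed beforehand, each library held 3 kinds of barcode. The kinds were formed on these same counts, and oxidative phosphorylation genes were among the leading genes of deep clusters. Examples were NDUFA4 in the basal library, ATP5H at 2 h and COX5A at 4 h. Their low level in MALAT1-rich barcodes is therefore partly built into the kinds and is no independent test. Against random lists matched on length, oxidative phosphorylation genes in MALAT1-rich barcodes had gaps of -0.85 or lower. Because genes of this list helped to form the kinds, these gaps cannot decide whether transcript length plays a part. Loss of cytoplasm from the MALAT1-rich barcodes predicted that mRNAs translated in the cytosol would be depleted against those at the endoplasmic reticulum, and oxidative phosphorylation genes lay below lysosome genes by -1.65 to -2.22 in the 4 libraries. That gap goes with loss of cytoplasm but does not test it apart from how the kinds were formed. MALAT1-rich barcodes held mitochondrially encoded RNAs 1.65 to 1.98 above deep barcodes. These are ratios of shares between kinds formed on the same counts, so they do not tell damaged cells from bare nuclei. MT-RNR2-rich barcodes also showed a gap of oxidative phosphorylation below lysosome genes, of -1.12 to -1.43. Free RNA in droplets without a cell cannot be told apart from cells in either the MALAT1-rich or the MT-RNR2-rich kind. The median Fano factor of abundant genes was lowest at 1.12 in MT-RNR2-rich barcodes, at 4 h. In MALAT1-rich barcodes it was 1.19 at the lowest, in the basal library, and 1.41 at the highest, at 4 h. These values lay above the 0.975 to 1.00 of a single simulated profile of these kinds. The lowest value of each kind lay below the 1.24 to 1.58 of deep barcodes.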
